A study of Mus musculus with 12 samples.

How the data were processed

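RNA was sequenced from a primary line of mouse fibroblasts (MMF), which per the labels came from the mammary fat pad of a B6 animal. The 12 libraries form 4 groups of 3. The doxorubicin group received 100 nM of this DNA-damaging topoisomerase poison for 24 h and was lysed on day 7. The hydrogen peroxide group received 750 uM of the oxidant for 2 h on 3 occasions with 48 h of recovery, and was lysed on day 6. Each treatment had its own water vehicle group, which the labels say was split routinely to keep the cells at a healthy density. Treated and vehicle cells therefore differed in passaging as well as in treatment. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

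The deposited table gives CPM (counts per 1e+06 reads assigned to genes), made by the authors from reads sequenced on a NovaSeq instrument. The processing notes of the submitters name bcl2fastq, DRAGEN and the mm10 build without versions. The counting method and the annotation release are not given in the sources used here. The table held 55774 lines, of which 287 repeated a gene identifier. All 168 repeated identifiers carried identical values, and 1 line of each was kept, leaving 55487 genes. Each library then summed to 1e+06, and 0 columns of values were left unmapped. Of the identifiers, 55141 (99.4%) were found in GENCODE mouse release M21 on GRCm38/mm10, which gave positions, gene classes and transcript sequences.

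Depth was read from the step between values, which is the CPM of a single read. Estimated depths ran from 17.3 to 37.6 M (1e+06) reads per library. All values were multiples of a hundredth of a read (100%, tolerance 0.02 of a hundredth), but only 74.6 to 79.8% of values up to 20 reads were whole reads, at a tolerance of 0.001 read. The counts behind the table were thus estimates, and whole reads could not be recovered. The planned tests with count models needed whole reads and were not run. A floor of 3 reads corresponded to 0.0798 to 0.173 CPM per library, which covers counting error only.

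Genes with at least 1 CPM in at least 3 of the 12 libraries were tested (13280 genes). Values were taken as log2(CPM + 1), so fold changes of genes with low values are understated. A single limma model (version 3.58.1 in R 4.3.3) with a mean-variance trend was fitted to the 4 groups, with 8 residual degrees of freedom and a median of 3.07 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were each treatment against its own vehicle, the difference between these effects, and the vehicle groups against each other. Overlap of the treatment effects was counted against the number expected for independent lists. Correlations of fold changes are across genes, which are not independent replicates. Prepared tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

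The comparisons, 27 gene lists, the rule for named genes and 27 alternative settings were chosen before the data were examined. Of the list members, 718 were matched to the table and 1 (Raet1a) was not. Lists were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the 27 lists of each comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance in a single direction, were run beside it. For called lists the adjusted p was larger with an estimated correlation, so very small values rest on the preset. Counts of list members are adjusted over all tested genes, with the count adjusted over the list alone where it differs. Named genes were an 8-gene panel (Cdkn1a, Cdkn2a, Cdkn2b, Lmnb1, Mki67, Il6, Col1a1 and Acta2), and for each treatment the 4 largest increases and 4 largest decreases with an adjusted p below the threshold, at least 5 CPM in the higher group, no overlap between libraries and no predicted gene model. The 2 members with the smallest adjusted p from each of the 10 lists with the smallest camera p were added. For the difference between treatments the 4 largest differences each way were named, with no overlap rule. Other genes in the text are list members chosen as examples after their values were seen. Some list members are not reported by name here.

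The alternatives covered pseudocounts of 0.1 and 2, other filters, 3 other scalings, limma without the trend, array weights, separate fits of each experiment, a replicate block, stricter thresholds, the other list tests, and leaving out each library in turn. After the data were examined, 5 settings were added: a correction of each library for transcript GC content, leaving out 2 libraries that deviated together, leaving out these and doxorubicin replicate 1, limma voom on estimated reads, and a covariate for the main direction in which libraries of the same group differed. GC content was available for 99.9% of tested genes. Sequence shared between genes was measured as the percentage of 50-base windows of a gene's longest transcript found in transcripts of other genes. Matches on either strand counted, so genes that overlap on opposite strands also count as sharing sequence.

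The procedure was tested on simulated data with 50 genes changed at each fold and 13004 genes in the test. For a single treatment, 54%, 86%, 94% and 100% of genes changed by 1.5, 2, 4 and 8-fold were recovered. Of 12804 unchanged genes 14 were called, among 181 calls. For the difference between treatments the shares were 34%, 64%, 94% and 100%, with 8 unchanged genes among 154 calls. A simulated comparison with no changed gene gave 0 calls. Noise was drawn independently for each gene, few genes changed, and none of the changed genes had low values. The real libraries deviated in many genes together, so these rates do not measure errors under such deviations.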

Results

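The transcriptomes of cultured mouse mammary fibroblasts were measured by RNA sequencing after doxorubicin or hydrogen peroxide, which the series describes as inducers of senescence, and after their water vehicles. Each of the 4 groups held 3 libraries. Estimated depth, in M (1e+06) reads, was 21.5 to 37.6 M reads in the doxorubicin group, 19.5 to 21.9 M reads in its vehicle group, 21.4 to 32.4 M reads in the peroxide group and 17.3 to 20.99 M reads in its vehicle group. Within groups, libraries correlated across genes at r = 0.973 to 0.996 on the log2(CPM + 1) scale. The first principal component held 52.8% of the variance and separated treated from vehicle libraries. The second held 23.7%, and along it libraries of the same group were spread, with 3 libraries far from the others of their groups. Scores on it were 48.2 for peroxide replicate 2 against 16.8 and 14.2, 37.8 for doxorubicin vehicle replicate 3 against 6.67 and 5.21, and 0.0133 for doxorubicin replicate 1 against -39.9 and -29.5.

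**Figure D1:**
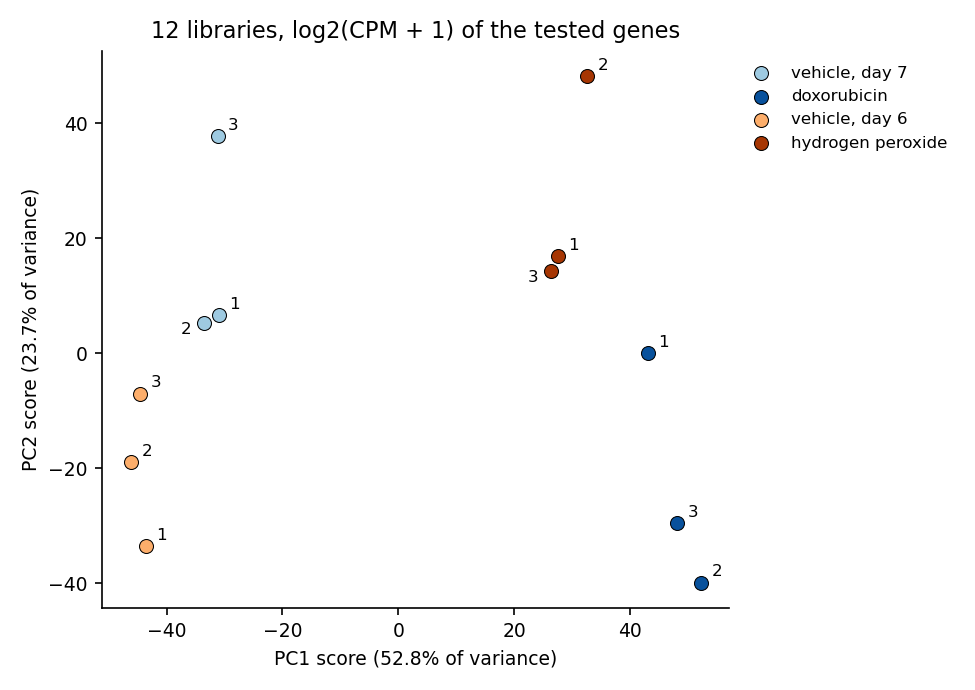
Principal components of log2(CPM + 1) values over the tested genes, with 1 point per library, coloured by group and numbered by replicate (n = 3 per group). Treated and vehicle libraries separate on the first component (52.8% of variance), and libraries of the same group spread along the second (23.7%).

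The first comparison asked how doxorubicin-treated fibroblasts differed from their vehicle group. The largest increases by the rule for named genes were in the interferon-stimulated genes Isg15, Usp18, Ifit3 and Ifit1, with Isg15, a ubiquitin-like protein of the antiviral response, at 304 ± 11.6 CPM against 2.60 ± 0.287 (SD, n = 3). Genes of the cell cycle fell, and Mki67, a marker of proliferating cells, was at 18.4 ± 1.38 against 76.6 ± 5.05 CPM (SD, n = 3). Cdkn1a, which encodes the cell-cycle inhibitor p21, rose from 208 ± 59.2 to 981 ± 30.2 CPM (SD, n = 3). Contractile, matrix and chemokine genes rose, and genes of cholesterol synthesis fell. In all, 6627 of 13280 genes changed, 2937 upward and 3690 downward, and by at least 1 log2 unit the split was 1185 upward and 529 downward. The upward share of all changed genes was 44.3%, and 50.9% when libraries were rescaled by median-of-ratios factors.

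Of the panel, Cdkn1a (ENSMUSG00000023067, a protein-coding gene on chromosome 17 from 29090976 to 29100727, plus strand, mm10) rose by 2.27 ± 0.26 log2 units (SE, adjusted p = 2.65e-05). It shares 10.5% of its windows with a transcript of another gene model, so its values are less certain. Lmnb1, which encodes lamin B1 of the nuclear envelope (chromosome 18, 56707813 to 56753424), fell by 1.39 ± 0.16 log2 units (adjusted p = 2.81e-05), from 4.93 ± 0.619 to 1.26 ± 0.307 CPM (SD, n = 3). Mki67 (chromosome 7, 135689784 to 135716361) fell by 2.00 ± 0.08 log2 units (adjusted p = 1.07e-08). Il6, an inflammatory cytokine (chromosome 5, 30013114 to 30019981), rose by 1.94 ± 0.17 log2 units (adjusted p = 3.71e-06), from 0.570 ± 0.276 to 5.02 ± 0.816 CPM (SD, n = 3). Acta2, the smooth muscle actin of myofibroblasts (chromosome 19, 34241090 to 34255590), rose by 1.60 ± 0.12 log2 units (adjusted p = 1.19e-06), from 907 ± 61.8 to 2763 ± 239 CPM (SD, n = 3). Col1a1, which encodes a chain of type I collagen, was at 3012 ± 733 against 2410 ± 49.6 CPM (SD, n = 3), a difference that did not pass the test (log2 fold change 0.30, adjusted p = 0.122). Cdkn2a (chromosome 4, 89274471 to 89294653) had 1 read in doxorubicin replicate 1 and 0 in the other 11 libraries, and its neighbour Cdkn2b had 0 reads in all 12. Over all libraries a floor of 3 reads allows up to 0.0104 CPM, so neither gene was detectable as a difference at this depth.

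Every one of the 39 tested genes of the type I interferon response rose (median log2 fold change 3.43, adjusted p = 1.22e-30). The estimated correlation between these genes was 0.484, far above the preset, and the call was kept at a much larger value (adjusted p = 0.0227 with an estimated correlation). Isg15 rose by 6.41 log2 units, Usp18, which limits interferon signalling, by 6.36, Ifit1 by 6.14 and Bst2, an antiviral membrane protein, by 4.04. Ifit3 was up by 6.34, a value that is uncertain because it shares 51.2% of its sequence windows with other transcripts, mainly of Ifit3b. Oas2, an antiviral RNA sensor, was listed at 0 in all vehicle libraries and at 35.1 ± 3.69 CPM with doxorubicin (SD, n = 3). Of 20 tested genes of antigen presentation by MHC class I, 15 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 5.45e-08). They included the immunoproteasome subunit Psmb8 (4.48), the peptide transporter subunit Tap1 (3.44) and H2-K1 (2.65). Of 16 complement genes 11 rose and 1 fell (adjusted p = 4.06e-06), with Cfb up by 5.19 and C4b by 4.66. Of 21 ligands of lymphocyte and natural killer receptors, 11 rose and 3 fell (11 and 4 adjusted over the list alone, adjusted p = 0.00242), among them the adhesion molecule Icam1 (4.13) and the checkpoint ligand Cd274 (2.07). That call was lost with an estimated correlation (adjusted p = 0.05003 with an estimated correlation, just above the threshold).

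Of 23 senescence-associated cytokines and chemokines, 20 rose and 2 fell (median 1.88, adjusted p = 4.44e-10). The monocyte attractants Ccl8 and Ccl2 rose by 4.46 and 2.65, and Ccl11, which attracts eosinophils, by 4.23. The secreted phosphoprotein Spp1 fell by 0.77. Of 23 proteases and inhibitors 17 rose and 1 fell (adjusted p = 1.97e-08), with the metalloproteinase inhibitor gene Timp3 up by 2.05 and gelatinase Mmp2 by 1.24. Timp3 shares 36.3% of its windows with other transcripts. Of 28 growth factors and binding proteins 18 rose and 3 fell (19 and 3 adjusted over the list alone, adjusted p = 1.94e-05), with Igfbp3 up by 2.79 and Hbegf by 1.70. Of 35 p53 target genes 26 rose and 1 fell (median 0.87, and 0.86 without Perp, which is at 0 in a group, adjusted p = 1.88e-10). Mdm2, which targets p53 for degradation, rose from 38.4 ± 1.61 to 323 ± 36.4 CPM (SD, n = 3). The proapoptotic gene Pmaip1 rose by 3.77 and the death receptor gene Fas by 2.54.

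Proliferation genes fell together. In the mitosis list 37 of 42 genes fell and 0 rose (median -1.52, adjusted p = 1.84e-19), including the spindle gene Nusap1 (-1.93) and the cyclin gene Ccnb1 (-1.82), which shares 42.1% of its windows with other transcripts. In the DNA replication list 37 of 46 fell and 2 rose (adjusted p = 3.77e-13), with the DNA ligase gene Lig1 at -1.59 and the clamp loader gene Rfc4 at -1.42. Of 22 genes of homologous recombination and Fanconi anaemia repair 20 fell and 0 rose (adjusted p = 1.09e-09), with Rad54b at -1.59 and Rad54l at -1.37. Of 17 nuclear lamina and chromatin factors 16 fell and 0 rose (adjusted p = 7.62e-11, and adjusted p = 0.0127 with an estimated correlation). They included the chromatin proteins Hmgb3 (-2.28) and Hmgb2 (-2.18) and the histone methyltransferase gene Ezh2 (-1.27). Hmgb3, Hmgb2, Rad54l and Rfc4 share 34.2, 21.9, 21.03 and 11.1% of their windows with other transcripts, so their values are less certain. Of 24 cholesterol synthesis genes 22 fell and 0 rose (0 and 23 adjusted over the list alone, median -1.87, adjusted p = 7.38e-15). The thiolase gene Acat2, which shares 45.9% of its windows, was at -2.47 and the sterol carrier gene Stard4 at -2.36.

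Of 24 myofibroblast contractile genes 23 rose and 1, Tagln2, fell (median 1.66, adjusted p = 1.60e-11). Calponin Cnn1 rose by 3.73, the light chain gene Myl9 by 2.71 and Actg2 by 2.49. Tagln rose by 2.89 and shares 48.3% of its windows. Of 44 other matrix proteins and collagen processing genes 36 rose and 1 fell (38 and 1 adjusted over the list alone, adjusted p = 7.38e-15), with tenascin Tnc up by 3.49, thrombospondin Thbs1 by 3.26 and fibronectin Fn1 by 1.93. Of 17 interstitial collagens 10 rose and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.00670), a call that was lost with other settings (adjusted p = 0.276 with an estimated correlation). Col8a1 rose by 2.72 and Col3a1 by 1.07. Of 18 basement membrane genes 12 rose and 1 fell (adjusted p = 1.89e-05), with Lama4 up by 3.60. Of 17 fibroblast identity genes 10 rose and 3 fell (adjusted p = 0.00823, and adjusted p = 0.0699 with an estimated correlation), with Pdgfra up by 0.96 and S100a4 down at -0.89.

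Of 37 lysosomal genes 21 rose and 0 fell (adjusted p = 1.29e-05), with Glb1, the lysosomal beta-galactosidase, up by 0.80 and cathepsin Ctsd by 1.14. Of 44 NRF2 and antioxidant genes 12 rose and 17 fell (12 and 18 adjusted over the list alone). That list was not called (adjusted p = 0.699, with a median of -0.04, a mean of 0.13 and a downward test), although heme oxygenase Hmox1 rose by 1.25 and Nqo1 fell by 0.99. Of 27 endoplasmic reticulum stress and ATF4 targets 2 rose and 8 fell (1 and 8 adjusted over the list alone, adjusted p = 0.204), with the serine synthesis gene Psat1 at -1.46. Of 6 cyclin-dependent kinase inhibitors 1, Cdkn1a, rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.473). The genes that fell were Cdkn3 (-1.96), a phosphatase gene expressed in cycling cells, Cdkn1b (-0.99) and Cdkn2c (-0.63).

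The largest decreases by the rule for named genes were in Trarg1 (-3.84), a regulator of glucose transporter trafficking, Aldoc (-3.43), a glycolytic aldolase, Avil (-3.02), an actin-binding protein, and Sparcl1 (-2.92), a matrix protein. Aldoc was at 1.92 ± 0.202 against 30.4 ± 1.82 CPM (SD, n = 3).

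Markers of other cell types were mostly low. Of 16 epithelial markers 2 were tested (1 higher and 1 lower, adjusted p = 0.516), with Krt19 at a mean of 113 CPM and down at -1.08. Of 12 endothelial markers 2 were tested (1 and 1, adjusted p = 0.654), with Tek at 20.52 CPM. Of 12 adipocyte markers 8 were tested (3 higher and 5 lower, adjusted p = 0.356), and Lpl, at a mean of 1693 CPM, fell by 0.69. The 3 tested of 16 leukocyte markers rose (adjusted p = 0.0377, and adjusted p = 0.124 with an estimated correlation), with Csf1r at a mean of 11.03 CPM and Lyz2 at 7.55. Of 6 tested pericyte and Schwann cell markers 4 rose (adjusted p = 0.0246, and adjusted p = 0.111 with an estimated correlation), with S100b at 25.6 CPM. The leukocyte call was also lost without doxorubicin replicate 1 (adjusted p = 0.0772) or its vehicle replicate 2 (0.0545), and the pericyte call without doxorubicin replicate 1 (0.156), 2 (0.0940) or 3 (0.0871), or without the 3 libraries that stood apart (0.215). Further losses were those of the leukocyte call with no filter (0.145), a filter of 5 CPM (0.0749) or GC correction (0.0614), and of the pericyte call with array weights (0.0641).

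**Figure D2:**
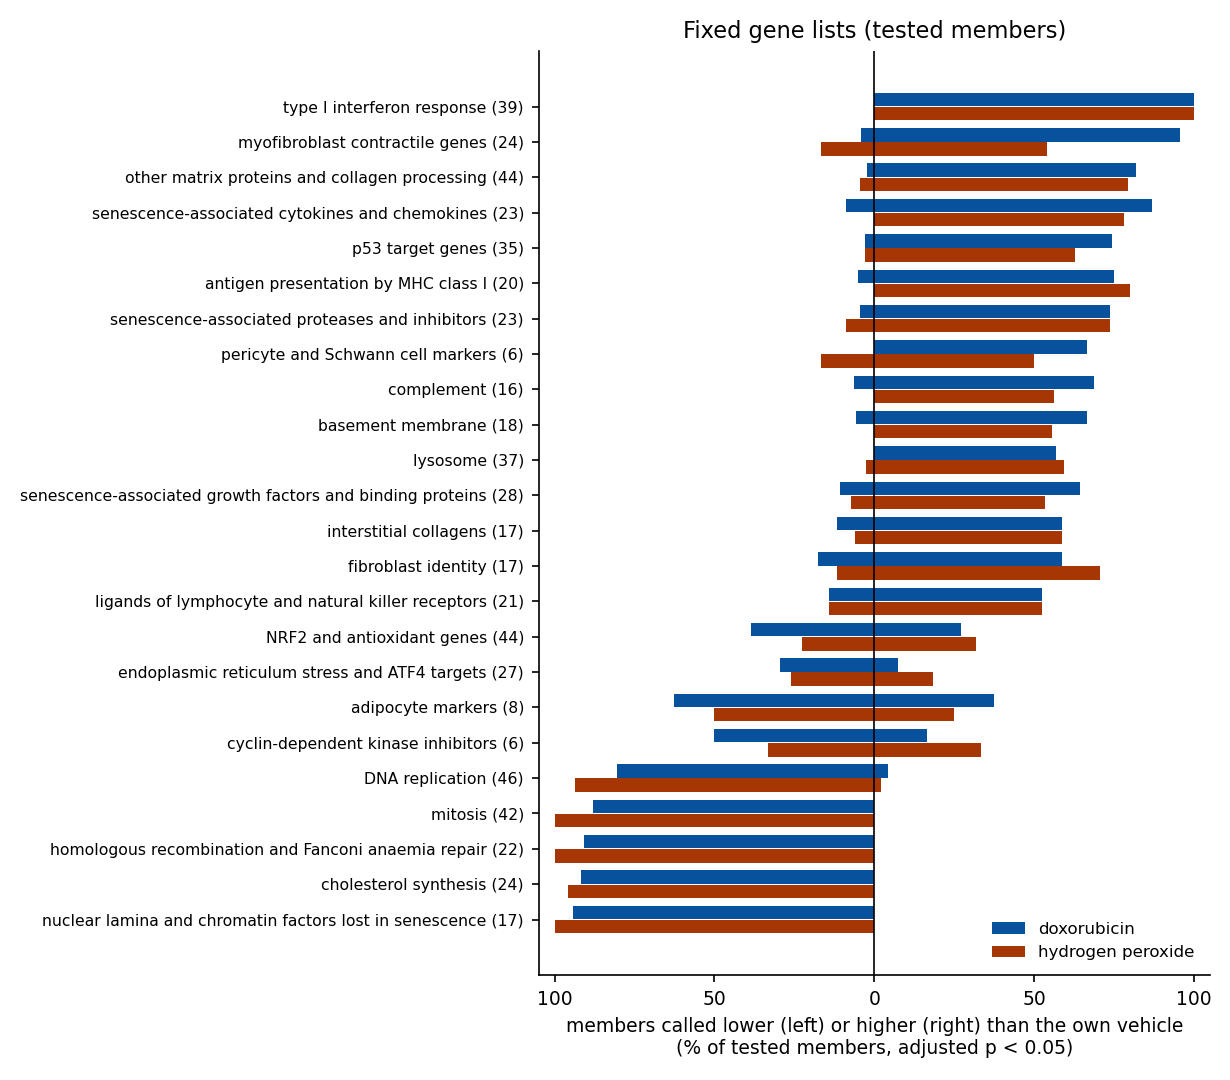
Percentage of the tested members of each gene list called higher (to the right) or lower (to the left) at an adjusted p below 0.05, for each treatment against its own vehicle (n = 3 libraries per group). Bars are shares of genes and carry no error, and only lists with at least 6 tested members are drawn. All 39 interferon genes were higher with either treatment, and at least 37 of 42 mitosis genes were lower.

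The second comparison asked how peroxide-treated fibroblasts differed from their own vehicle group. The largest increases by the rule for named genes were in Isg15, Usp18, Ccl8 and Pamr1, with Isg15 at 115 ± 52.2 against 1.25 ± 0.273 CPM and Ccl8 at 78.4 ± 1.48 against 1.01 ± 0.147 CPM (SD, n = 3). Mki67 was at 34.1 ± 2.10 against 125 ± 6.96 CPM (SD, n = 3), and every tested gene of mitosis, recombination repair and the nuclear lamina list fell. Matrix genes rose, with decorin Dcn, a proteoglycan that binds collagen, at 538 ± 29.0 against 17.6 ± 3.06 CPM (SD, n = 3). In all, 6733 genes changed, 3632 upward and 3101 downward, and by at least 1 log2 unit the split was 973 upward and 875 downward.

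Cdkn1a rose by 1.23 ± 0.26 log2 units (SE, adjusted p = 0.00198), from 246 ± 11.5 to 606 ± 206 CPM (SD, n = 3). Lmnb1 fell by 1.48 ± 0.16 log2 units (adjusted p = 1.63e-05) and Mki67 by 1.85 ± 0.08 (adjusted p = 2.61e-08). Smaller increases passed the test for Il6 (0.58 ± 0.17, adjusted p = 0.0145, 2.48 ± 0.435 against 1.33 ± 0.342 CPM), Col1a1 (0.52 ± 0.15, adjusted p = 0.0135) and Acta2 (0.38 ± 0.12, adjusted p = 0.0219). The Il6 call was lost without peroxide replicate 3 (adjusted p = 0.0520) or its vehicle replicate 3 (0.0565), with a range of 0.00860 to 0.0821 over its alternatives. The Col1a1 call was lost without peroxide replicate 3 (0.0518) or vehicle replicate 2 (0.0564), with a range of 0.00147 to 0.0610. The Acta2 call was lost without peroxide replicate 2 (log2 fold change 0.24, adjusted p = 0.0610), vehicle replicate 1 (0.0752) or vehicle replicate 3 (0.0602), with a range of 0.00591 to 0.121. Cdkn2a and Cdkn2b had 0 reads in these 6 libraries.

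All 39 interferon genes rose (median 2.57, adjusted p = 7.95e-22), a call that was lost in 1 list test (adjusted p = 0.0502 with an estimated correlation). Isg15 rose by 5.61, Usp18 by 5.54, Xaf1, an interferon-induced proapoptotic gene, by 4.46 and Bst2 by 3.62. Of 20 MHC class I genes 16 rose and 0 fell (adjusted p = 4.28e-06), with the light chain gene B2m up by 1.54 and the proteasome activator Psme2 by 1.10, although Psme2 shares 59.3% of its windows, mainly with Psme2b. Of 16 complement genes 9 rose and 0 fell (adjusted p = 4.44e-05), with C4b up by 4.09 and Cfb by 3.07. Of 21 lymphocyte and natural killer ligands 11 rose and 3 fell (adjusted p = 0.0206, and adjusted p = 0.123 with an estimated correlation). Of 23 cytokines and chemokines 18 rose and 0 fell (median 0.64, adjusted p = 1.32e-05), led by Ccl8 (5.30) and Ccl11 (2.92), while Cxcl1 did not pass the test (-0.19). Of 23 proteases and inhibitors 17 rose and 2 fell (adjusted p = 1.08e-06), with the plasminogen activator Plat up by 2.19, gelatinase Mmp2 by 1.95 and Timp3 by 1.76. Of 28 growth factors 15 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p = 0.00158), including Igfbp5 (3.91). Of 35 p53 targets 22 rose and 1 fell (median 0.72, adjusted p = 1.32e-05), with Fas up by 2.50, Pmaip1 by 2.31 and Mdm2 by 1.61.

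All 42 mitosis genes fell (median -1.48, adjusted p = 2.10e-22), among them the cohesin protector gene Sgo1 (-1.84) and Ccnb1 (-1.55). Of 46 replication genes 43 fell and 1 rose (adjusted p = 6.03e-21), with the initiation factor Mcm10 at -1.96 and Lig1 at -1.79. All 22 recombination and Fanconi genes fell (adjusted p = 2.93e-11), with the nuclease gene Exo1 at -1.82 and Rad54l at -1.32. All 17 lamina and chromatin factors fell (adjusted p = 2.11e-12), with Hmgb3 at -2.15 and Hmgb2 at -1.84. Of 24 cholesterol synthesis genes 23 fell and 0 rose (0 and 24 adjusted over the list alone, adjusted p = 6.35e-17), with Idi1, which shares 30.5% of its windows, at -2.69 and Stard4 at -2.51. The largest decreases were Id3 (-3.45), an inhibitor of differentiation factors, the ribonucleotide reductase gene Rrm2 (-3.39), the oestrogen receptor gene Gper1 (-3.38) and the transcription factor gene Irf5 (-3.29). Values of Id3 (44.8 ± 34.0 against 373 ± 121 CPM) and Rrm2 (122 ± 76.4 against 1176 ± 456 CPM, SD, n = 3) were widely spread in both groups, and peroxide replicate 2 held the lowest, at 7.91 CPM for Id3 and 48.4 CPM for Rrm2.

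Of 44 other matrix genes 35 rose and 2 fell (adjusted p = 3.43e-12), with Dcn up by 4.87 and Prelp, a leucine-rich proteoglycan, by 4.53. Of 17 interstitial collagens 10 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00288, and adjusted p = 0.252 with an estimated correlation), with Col3a1 up by 2.13. Of 18 basement membrane genes 10 rose and 0 fell (adjusted p = 0.000901), and Lama4 rose by 5.04. Of 17 fibroblast identity genes 12 rose and 2 fell (adjusted p = 0.000267), with Cd34 up by 2.89 and Fap by 2.03. The contractile list went both ways, with 13 of 24 genes higher and 4 lower (median 0.36, adjusted p = 0.0279). Tagln rose by 0.68 and Actg2 by 0.72, while the tropomyosin gene Tpm4 fell by 1.13. Its call was lost without vehicle replicate 3 (adjusted p = 0.0643) and in 1 list test (adjusted p = 0.214 with an estimated correlation). Of 37 lysosomal genes 22 rose and 1 fell (adjusted p = 6.44e-06), with cathepsin Ctsk up by 1.45 and mannosidase Man2b1 by 1.35. Pamr1, which encodes a secreted peptidase-like protein and is in none of the lists, rose by 5.11, from 0.195 ± 0.122 to 40.3 ± 5.34 CPM (SD, n = 3).

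The NRF2 list was again not called, with 14 of 44 genes higher and 10 lower (14 and 11 adjusted over the list alone, adjusted p = 0.862, with a median of -0.03, a mean of 0.10 and an upward test), while Hmox1 rose by 1.13 and the cystine transporter gene Slc7a11 fell by 1.24. Of 27 endoplasmic reticulum stress genes 5 rose and 7 fell (adjusted p = 0.501), and of 6 cyclin-dependent kinase inhibitors 2 rose and 2 fell (adjusted p = 0.666). None of the lists of other cell types was called. Of 8 tested adipocyte markers 2 rose and 4 fell (3 and 4 adjusted over the list alone, adjusted p = 0.409), and Lpl rose by 1.08. Of 3 leukocyte markers 2 rose and 1 fell (adjusted p = 0.541), of 6 pericyte and Schwann cell markers 3 rose and 1 fell (adjusted p = 0.294), of 2 epithelial markers 1 rose and 1, Krt19, fell by 2.31 (adjusted p = 0.862), and of 2 endothelial markers 1, Tek, rose by 1.65 (adjusted p = 0.294).

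**Figure D3:**
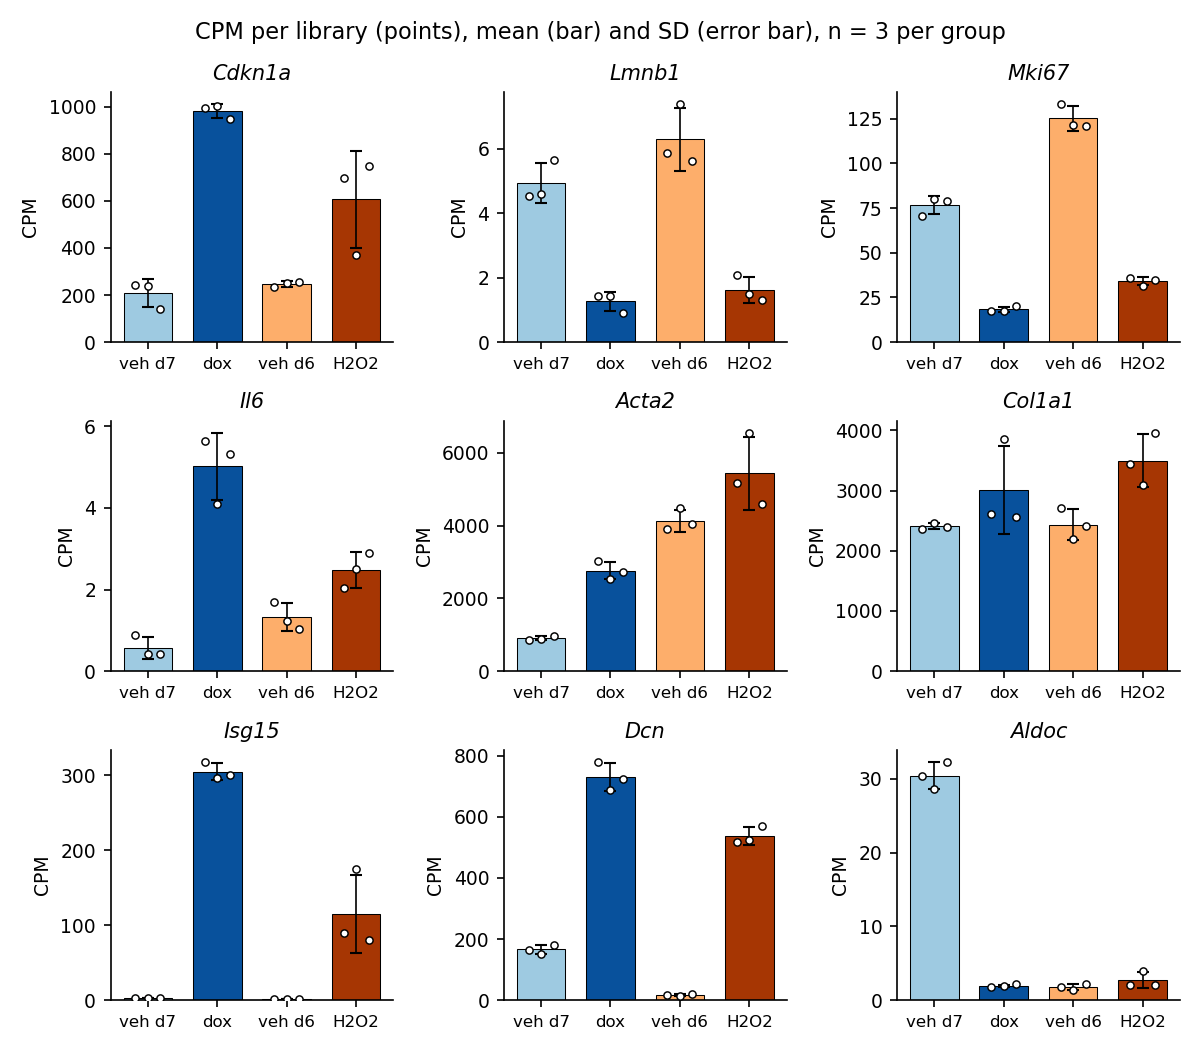
CPM of 9 genes in each library (points), with the group mean (bar) and SD (error bar), n = 3 libraries per group, where veh d7 and veh d6 are the vehicles of the doxorubicin (dox) and peroxide (H2O2) experiments. Isg15 and Cdkn1a were higher and Mki67 and Lmnb1 lower with either treatment, while Aldoc fell with doxorubicin from 30.4 to 1.92 CPM and was at 2.75 against 1.82 CPM in the peroxide experiment.

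The treatments were next compared gene by gene. Both raised 1729 genes, against 803 expected for independent lists, and both lowered 1791, against 862 expected. These 3520 genes included all 39 tested interferon genes, 37 mitosis genes, 20 recombination and Fanconi genes and 16 lamina and chromatin factors, and in 938 of the 3520 the size of the change differed between the treatments. Opposite changes were found in 138 genes raised by doxorubicin and lowered by peroxide and in 340 the other way, where 686 and 1009 were expected. Across genes the fold changes correlated at r = 0.49 (Spearman rho 0.40), and 64.2% of genes had the same sign. Treated and vehicle cells also differed in passaging in both experiments, so shared changes cannot be assigned to the treatments alone.

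The difference between the treatment effects passed the test in 4461 genes, 1796 with a higher fold change after doxorubicin and 2665 with a lower one. By at least 1 log2 unit the split was 1021 higher and 459 lower. The share with a higher fold change was 40.3%, and 52.0% when libraries were rescaled by median-of-ratios factors. With a covariate for the main direction in which libraries of the same group differed, 2046 genes passed the test. The 1796 genes with a higher fold change became 1098 without doxorubicin replicate 3, 1190 without its vehicle replicate 3 and 1142 without peroxide vehicle replicate 1. The contractile genes stood out, with a higher fold change after doxorubicin in 17 of 24 and a lower one in 0 (18 and 0 adjusted over the list alone, median difference 0.94, adjusted p = 7.51e-11). Tagln rose by 2.89 and 0.68 with doxorubicin and peroxide, Cnn1 by 3.73 and 0.74, and Acta2 by 1.60 and 0.38. Between the treated groups the list was not called, with 4 of the 24 genes higher and 8 lower after doxorubicin than after peroxide (adjusted p = 0.248). Acta2 was lower there, at 2763 ± 239 against 5437 ± 1004 CPM (SD, n = 3; log2 difference -0.96, adjusted p = 0.000426), as were Actg2 (-0.98) and Cnn1 (-1.14). Of 39 interferon genes 18 were raised more by doxorubicin and 1 less (22 and 1 adjusted over the list alone, median 0.67, or 0.55 without the 5 genes at 0 in a group, adjusted p = 1.07e-07). That call was lost in 1 list test (adjusted p = 0.436 with an estimated correlation). Of 23 cytokines and chemokines 12 had a higher and 3 a lower fold change after doxorubicin (15 and 4 adjusted over the list alone, median 1.07, adjusted p = 0.000128), including Cxcl1 (2.30 higher), Ccl2 (2.22) and Il6 (1.36), while the differences for Spp1 and Ccl8 were -1.84 and -0.85. Of 35 p53 targets 14 were higher and 4 lower (15 and 5 adjusted over the list alone, adjusted p = 0.00509, and adjusted p = 0.139 with an estimated correlation). Of 46 replication genes 16 were higher and 2 lower (17 and 2 adjusted over the list alone, adjusted p = 0.00106, and adjusted p = 0.120 with an estimated correlation), as in Mcm2, which fell by 2.48 with peroxide and did not pass the test with doxorubicin (-0.21). Between the treated groups 1 replication gene was higher and 28 were lower with doxorubicin (adjusted p = 1.23e-06). In the same comparison 37 of 39 interferon genes were higher and 0 lower, 13 of 23 cytokines and chemokines were higher and 2 lower, and 8 of 35 p53 targets were higher and 2 lower (adjusted p = 5.09e-30, 1.00e-07 and 0.00339, and adjusted p = 0.0506, 0.00336 and 0.0663 with an estimated correlation).

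The largest differences upward were in Gadd45g (5.31, with fold changes of 4.01 and -1.30), Tnfrsf12a (5.26, fold changes 2.73 and -2.53), Id1 (4.77, 1.96 and -2.81) and Id3 (4.71, 1.26 and -3.45). The largest downward were in Aldoc (-3.81, fold changes -3.43 and 0.38), Vsnl1, a neuronal calcium sensor (-3.80, -1.83 and 1.97), Igfbp5, a binding protein of insulin-like growth factors (-3.51, 0.40 and 3.91), and Sparcl1 (-3.28, -2.92 and 0.36). Replicates of these upward genes were widely spread (Id1 was at 15.1 ± 11.6 CPM with doxorubicin, SD, n = 3). With the within-group covariate the differences of Gadd45g, Id1 and Id3 were 2.23, 2.34 and 1.55 and no longer passed (adjusted p = 0.0510, 0.113 and 0.147), while that of Tnfrsf12a was 2.49. In the panel the difference was 1.22 for Acta2 (adjusted p = 0.000632), 1.36 for Il6 (adjusted p = 0.00227) and 1.04 ± 0.36 for Cdkn1a (adjusted p = 0.0461), and it did not pass for Lmnb1 (0.08), Mki67 (-0.15) or Col1a1 (-0.22). The Cdkn1a call was lost without any of 8 of the libraries, most of all without doxorubicin vehicle replicate 3 (0.78, adjusted p = 0.0954), over a range of 0.00351 to 0.662 in its alternatives. Without peroxide replicate 2 and doxorubicin vehicle replicate 3 together the difference was 0.46, and without doxorubicin replicate 1 as well it was 0.45 (adjusted p = 0.00351) and that of Id3 3.07. In the fit with a replicate block, paired by replicate number, 3272 genes differed in place of 4461 and the Cdkn1a call ended.

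The other lists did not differ past the threshold. Fibroblast identity was nearest (2 higher and 9 lower of 17, adjusted p = 0.0615, and adjusted p = 0.362 with an estimated correlation) and was called in 11 of 30 alternatives. These were those without doxorubicin replicate 2 (0.0474), its vehicle replicates 2 (0.0478) or 3 (0.0427), or peroxide vehicle replicate 3 (0.0335), and those with a pseudocount of 0.1 (0.0413), no filter (0.00969), median-of-ratios factors (0.0484), GC correction (0.0389), voom (0.0455), the within-group covariate (0.0299) and fry (5.89e-05). For mitosis 4 of 42 were higher and 14 lower (adjusted p = 0.237, median -0.21, mean 0.07), and for lysosome 5 and 14 of 37 (adjusted p = 0.273, median -0.27, mean 0.12). Median and mean also differed in sign for NRF2 genes (-0.16 and 0.02), recombination repair (-0.07 and 0.03), lamina factors (-0.02 and 0.14) and endoplasmic reticulum stress (-0.06 and 0.17), and the inhibitor list had a downward test with a median of 0.02.

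**Figure D4:**
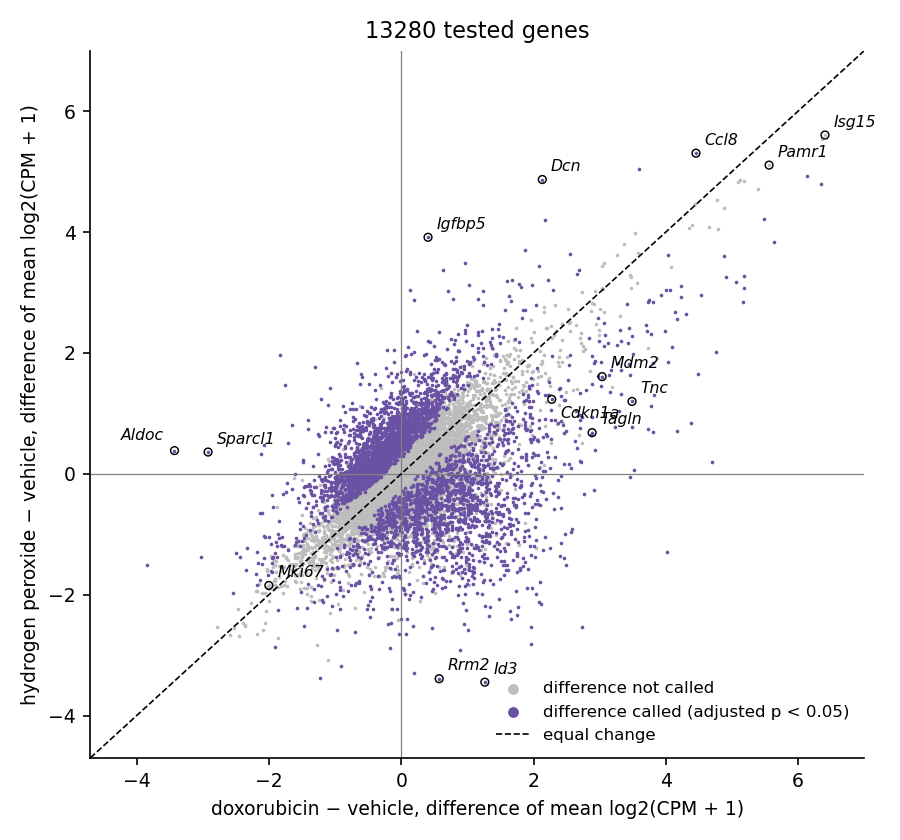
Log2 fold change of each of the 13280 tested genes after peroxide (vertical axis) against that after doxorubicin (horizontal axis), each against its own vehicle (n = 3 libraries per group). The dashed line marks equal change, and purple points are the 4461 genes whose change differed between the treatments (r = 0.49 across all genes).

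The vehicle groups came from separate experiments harvested on days 7 and 6, and 3719 genes differed between them, 2001 higher and 1718 lower in the doxorubicin vehicle, and 450 by at least 1 log2 unit. With array weights 5666 genes differed. Contractile genes were lower in that group in 19 of 24 cases and higher in 0 (adjusted p = 2.21e-14), with Cnn1 at -4.13, Actg2 at -2.75, Tagln at -2.47 and Acta2 at -2.19 (907 ± 61.8 against 4136 ± 302 CPM, SD, n = 3). Replication genes were lower in 40 of 46 (adjusted p = 2.09e-18) and mitosis genes in 37 of 42 (adjusted p = 1.14e-16), with Mki67 at 76.6 against 125 CPM. Higher in the doxorubicin vehicle were 20 of 37 lysosomal genes (adjusted p = 9.23e-07), 8 of 17 identity genes (adjusted p = 4.18e-05) and 19 of 39 interferon genes (adjusted p = 2.43e-07, and adjusted p = 0.355 with an estimated correlation), and the genes Aldoc (3.49), Dcn (3.18), Anpep (3.04) and Igfbp5 (2.74). The list tests of the vehicle groups against each other, and of the treated groups against each other, were chosen after the data were examined. Of the 4461 genes whose treatment effects differed, 1590 also differed between the vehicle groups and not between the treated groups, 1429 between the treated groups and not the vehicles, 741 between both and 701 between neither.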

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

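The settings without 2 or 3 libraries, the GC correction, the test of library depth and the test with a within-group covariate were chosen only after the result was seen.

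The results in this part stand out because the effect of doxorubicin and that of peroxide, each against its own vehicle, differed in a direct test of the difference. This held for 4461 genes, for 5 of the 27 gene lists and for 38 of the 57 named genes that were tested. Among lists, the median difference of the log2 fold changes was 1.07 for cytokines and chemokines, 0.94 for contractile genes, 0.67 for interferon genes, 0.42 for p53 targets and 0.23 for DNA replication. The contractile list was not called between the treated groups (adjusted p = 0.248 by camera), and 19 of its 24 genes were lower in the doxorubicin vehicle. In DNA replication 40 of 46 genes were lower in that vehicle, and between the treated groups 28 were lower and 1 higher with doxorubicin. The differences of these lists thus lay with the vehicle groups. The interferon, cytokine and p53 lists were also called higher in the doxorubicin than in the peroxide group. With an estimated correlation only the cytokine call between the treated groups was kept (adjusted p = 0.0506, 0.00336 and 0.0663 by camera, in that order). With the within-group covariate all 5 lists remained called (adjusted p = 4.82e-06, 3.32e-15, 1.74e-21, 0.0328 and 9.62e-07 by camera, in the order of the medians). That covariate was taken from the deviations of these same libraries and removes their main direction, and its scores also differ between groups. These p-values are therefore no independent support. With an estimated correlation between genes, and without the covariate, the calls of interferon genes, p53 targets and DNA replication were lost (adjusted p = 0.436, 0.139 and 0.120 with an estimated correlation), and those of the other 2 lists were kept (0.0184 for both).

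Among genes with a higher fold change after doxorubicin, the differences were 5.31 for Gadd45g, 5.26 for Tnfrsf12a, 4.77 for Id1, 4.71 for Id3, 3.96 for Rrm2 and 3.49 for Irf5. Interferon and chemokine genes followed, with 2.22 for Ccl2, 1.55 for Ifit3, 1.36 for Il6, 1.20 for Ifit1 and 0.41 for Bst2. For Oas2 the fitted difference was 2.33, which depends on the pseudocount because both vehicle groups were listed at 0. Contractile and matrix genes differed by 2.29 for Tnc, 2.20 for Tagln, 1.77 for Actg2, 1.22 for Acta2, 1.14 for Thbs1 and 0.29 for Timp3. The remaining higher values were 2.15 for Gper1, 1.43 for Mdm2, 1.04 for Cdkn1a, 0.45 for Mcm10 and 0.42 for Exo1. Lower fold changes after doxorubicin were found for Aldoc (-3.81), Vsnl1 (-3.80), Igfbp5 (-3.51), Sparcl1 (-3.28), Dcn (-2.74), Trarg1 (-2.33) and Avil (-1.65). The same held for the mitotic genes Nusap1 (-1.38) and Ccnb1 (-0.28), the chromatin gene Hmgb2 (-0.33), and for Ctsk (-0.94), Ccl8 (-0.85), Plat (-0.84), Man2b1 (-0.60) and Psme2 (-0.52).

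Leaving out each library in turn kept 31 of these 38 gene calls. Those of Cdkn1a, Exo1, Bst2, Timp3, Gper1, Ccnb1 and Hmgb2 were each lost without at least 1 library, with an adjusted p of up to 0.109 for Exo1, 0.0954 for Cdkn1a, 0.0917 for Ccnb1, 0.0912 for Bst2, 0.0877 for Gper1, 0.0869 for Timp3 and 0.0581 for Hmgb2. With the within-group covariate 27 of the 38 calls were kept and 11 were lost, none with a call in the opposite direction. The calls lost were those of Gadd45g (adjusted p = 0.0510), Id1 (0.113), Id3 (0.147), Gper1 (0.633), Cdkn1a (0.662), Mcm10 (0.0697), Exo1 (0.0587), Bst2 (0.121), Ccnb1 (0.343), Psme2 (0.115) and Man2b1 (0.0914).

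When the libraries were regrouped at random, 1 of 100 splits (drawn from 200) gave as many as 4461 differing genes, namely the real one. The highest other of those drawn gave 2595. This speaks only against treated and vehicle libraries being interchangeable. These splits mix treated and vehicle libraries, which puts the treatment effects into the spread within groups and can hold counts down. They do not test whether the effects were equal. The split with treated and vehicle exchanged in the peroxide experiment was not drawn and gives 7490 differing genes and 478 with the same direction. For the 5 lists whose change differed, 62 of 100 splits gave at least as many and the highest gave 21. These splits give no chance level for the number of lists. A mixed split holds treated and vehicle libraries in unequal numbers on its sides and so keeps part of the treatment effects. List tests can still pick this up, since the highest other split called 19 lists but 0 genes for either treatment. Whether the number of lists exceeds chance is therefore undecided. The 3520 genes changed in the same direction by both treatments were matched by 1 of 100 splits, the real one, with 0 in the highest other. This too speaks only against treated and vehicle libraries being interchangeable. Mixing the libraries of a treatment with those of its vehicle gave 0 genes for that treatment, which left no shared genes to count. It is therefore no test of whether the direction was shared. For genes changed by doxorubicin (6627 against 0 in the highest other split), by peroxide (6733 against 0) and between vehicles (3719 against 0), the 10 splits of 6 libraries are too few for a share under 0.05, with 1 of 10 in each case. The same limit applies to the lists called for doxorubicin (21 against 19, 1 of 10) and for peroxide (19 against 19, 2 of 10). For these lists too the mixed splits keep part of the treatment effect and give no chance level.

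A first pattern was that peroxide replicate 2 and doxorubicin vehicle replicate 3 deviated from their groups in the same genes, with a correlation of deviations across genes of 0.633, the highest of 54 pairs from different groups, and 307 genes at least 1 log2 unit lower in both where 20.7 were expected; the pattern was not theirs alone, with lower values for doxorubicin replicate 1 with peroxide vehicle replicate 3 (0.529, 86 genes) and with doxorubicin vehicle replicate 3 (0.399, 85 genes). The 307 genes had a median GC content of 53.3% against 49.2% over all genes, and a median transcript length of 2491 against 3217 bases, which was not corrected for and stays open. The tables argue against GC content as the whole cause, since after a correction for it the correlation was 0.668 and 277 genes were lower in both (271 of the 307), and against library depth, since the libraries lay on opposite sides of their groups (log2 depth ratios of 0.571 and -0.114, product -0.0654), and a swap of their labels, since each correlated more with its own group (differences of 0.0298 and 0.0403). A shared step in culture, handling or library preparation could account for the pattern, and it stays open because the labels give no batch, and no biological explanation was tested, since the libraries come from different treatments.

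A second pattern was the size of the difference between treatments. GC content is argued against as the whole cause, since 83.5% of the 4461 calls were kept after correction. The 100 genes highest on the direction of spread described next had a median GC content of 56.0% against 49.2%. Their median transcript length was 1792 against 3217 bases. Across all genes, however, the Spearman correlation of that direction was -0.028 with GC content and 0.097 with transcript length. A shift in the vehicle groups stays open for the 4461 genes as a whole, because 51.2% of them (2286) differed more between vehicles than between treated groups. For the contractile and replication lists the difference lay with the vehicle groups, as given above. The 2 deviating libraries also stay open as a cause, since 73.4% of calls were kept without them (87.1% without doxorubicin replicate 1 as well, all of them left out because they stood apart). A covariate for the main direction of spread within groups, which held 46.8% of that spread, kept 38.6% of calls, with a median ratio of the difference with and without it of 0.781 over all 4461 calls (0.990 in the 1723 kept and 0.609 in the 2738 lost, which the loss itself selects) and of its SE of 1.20, consistent with part of the difference lying along it. That direction (correlation with the difference across genes 0.69) may be technical or a state of the cells such as density, and dose, day of harvest and experiment all go with the treatment, so a biological difference between the treatments also remains open and untested.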

How the results depend on the processing

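Added settings (GC correction, 2 or 3 libraries left out, voom and the within-group covariate) were chosen after the data were examined. No gene or list call reversed under any of the 32 settings. The direction of most called genes turned with median-of-ratios factors for doxorubicin (44.3 to 50.9% higher) and the difference (40.3 to 52.0%), and with a minimum log2 fold change of 1 for these (69.1 and 69.0%) and between vehicles (53.8 to 48%). Among 82 gene results and 81 list results, 74 and 49 kept their side of the threshold throughout. The other gene results were Il6, Col1a1 and Acta2 for peroxide, and Cdkn1a, Col1a1, Gadd45g, Id1 and Id3 for the difference. Most of the 82 were named for large changes or small adjusted p, so their stability does not stand for all genes. With no filter, 84.1% of all doxorubicin calls, 85.4% of peroxide calls and 66.2% of difference calls were kept. These 82 are the 34 tested genes named for doxorubicin, 34 for peroxide and 14 for the difference, so most of the 38 named genes whose change differed are not among them for the difference. Of those 38 calls, 22 were kept in all 27 settings that refitted the difference without a stricter threshold, and 15 were lost in at least 1 of them, none with a call in the opposite direction: those of Cdkn1a, Gadd45g, Id1, Id3, Exo1, Bst2, Timp3, Gper1, Ccnb1, Hmgb2, Mcm10, Psme2, Man2b1, Ifit1 and Ifit3. That of Il6 was not tested at a filter of 5 CPM. A minimum log2 fold change of 1 left 1714 genes for doxorubicin, 1848 for peroxide, 1480 for the difference, 450 between vehicles and 776 in the same direction, which follows from its construction. An adjusted p under 0.01 left 1941 differing genes and 2042 between vehicles. Array weights, whose estimation did not converge fully, gave 5666 genes between vehicles. The 5 lists called for the difference became 9 without a filter, 2 with an estimated correlation and 12 with fry, which does not compare a list with other genes. The within-group covariate left 2046 differing genes and moved the correlation of fold changes from 0.49 to 0.70. Leaving out each library gave 5498 to 7194 genes for doxorubicin, 5679 to 6937 for peroxide, 3157 to 4998 for the difference, 2556 to 4484 between vehicles and 3088 to 3576 in the same direction, correlations of 0.420 to 0.565, and 19 to 21, 18 to 19 and 5 to 6 lists, 43 to 46 in all. The replicate block gave 5957, 6091, 3272 and 2868 genes, and replicate numbers did not pair samples, with correlations across genes of -0.311 to 0.194. The cause of these changes was not tested except where given. Planned count models were not run because whole reads were not recovered. Depth limits genes near the floor of 0.0798 to 0.173 CPM.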

Other observations

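The gene groups in the first paragraphs and the list tests on them were chosen only after their values were seen.

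Imprinted genes, which are expressed from 1 parental allele, changed in both directions and more often rose. Of 56 listed, 36 were tested, of which 15 rose and 7 fell with doxorubicin (adjusted p = 0.0138, and adjusted p = 0.0987 with an estimated correlation) and 16 rose and 8 fell with peroxide (adjusted p = 0.0534, which did not pass). The noncoding RNA Meg3 rose from 39.0 ± 5.57 to 191 ± 31.8 CPM with doxorubicin and from 50.0 ± 6.65 to 278 ± 33.3 CPM with peroxide (SD, n = 3). H19, near the floor in vehicles (0.0608 ± 0.105 and 0.0963 ± 0.167 CPM), was at 13.2 ± 2.58 and 6.88 ± 1.19 CPM (SD, n = 3). The transporter gene Slc22a18 rose by 2.30 and 3.05 log2 units and Peg3 by 0.90 and 1.41, while Peg10 fell by 0.65 and 0.75. Histone genes of the clusters, whose transcripts mostly lack a poly(A) tail, rose in 13 and fell in 3 of 19 tested with doxorubicin (adjusted p = 0.00168, and adjusted p = 0.103 with an estimated correlation) and rose in 7 and fell in 5 with peroxide (adjusted p = 0.824). Of 67 listed only these 19 passed the filter on low values. Some passed it mainly through the doxorubicin libraries, such as H4c8 at 13.4 against 0.173 CPM, so the upward count is partly set by the filter. H1f2 rose by 2.07 and 1.70 and H1f5 fell by 2.09 and 2.59 with doxorubicin and peroxide.

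All 6 tested gene models that lie in satellite-like repeats rose with both treatments (adjusted p = 1.23e-05 and 4.52e-05, and adjusted p = 0.103 for both with an estimated correlation). Gm10800 (chromosome 2, 98666547 to 98667301) was at 43.2 ± 10.2 against 0.252 ± 0.182 CPM with doxorubicin and at 31.8 ± 8.01 against 0.111 ± 0.0540 CPM with peroxide (SD, n = 3). The 6 models were chosen after their values were seen, so a rise in all of them is no independent evidence. Gm10800 passed the filter on low values only through treated libraries. These models share 17.1 to 85.0% of their windows with other transcripts, in Gm10801 mainly with Gm10800. Which copies were read is therefore uncertain, and the 6 models are not fully separate measurements. Of 616 tested processed pseudogenes, 26 rose and 311 fell with doxorubicin, and 32 rose and 149 fell with peroxide. Of all 13280 tested genes, 3690 fell with doxorubicin and 3101 with peroxide. These pseudogenes share a median of 78.5% of their windows with other transcripts, so which copies were read is uncertain here too. Genes of ribosomal proteins took 5.41 ± 0.546 against 7.76 ± 0.293% of CPM in the doxorubicin experiment and 6.29 ± 0.332 against 6.73 ± 0.304% in the peroxide experiment (SD, n = 3, exact permutation p = 0.1 and 0.2). Long intergenic noncoding RNAs took 0.624 against 0.467% of CPM in the doxorubicin experiment and 0.815 against 0.409% in the peroxide experiment (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give).

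Another pattern was that Cdkn2a and Cdkn2b, cell-cycle inhibitor genes often measured in senescence, were listed at about 0 in every library. Reads lost to near-identical genes are argued against, since 0% of their 50-base windows occur in other transcripts. Loss of the locus could also leave these genes silent. Between the nearest expressed neighbours, 1977359 bases apart, 2 of 17 genes had more than 3 reads over all libraries. These were Zfp352 and Gm12643, which start 944349 and 1763429 bases from the start of Cdkn2a. The nearer neighbour, Gm12606, had 652 reads and ends at 89273403, just before Cdkn2a starts at 89274471. A loss would thus have to spare Gm12606. Such a loss cannot be told apart from silencing, because 54.2% of 10195 silent protein-coding genes elsewhere also had at most 3 reads. The series describes both treatments as inducers of senescence, yet the treated groups showed no detectable rise, with 1 read of Cdkn2a and 0 of Cdkn2b over all libraries. No biological explanation was tested, since none of the groups expressed the genes.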
